A study of Mus musculus with 8 samples.

How the data were processed

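RNA of cultured, dissociated mouse hippocampal neurons was measured on 8 2-colour Agilent mouse expression arrays, 4 labelled as carrying Flag-tagged Nr4a1 and 4 labelled as carrying GFP. Per the labels' protocols, neurons grown for 10 days received a lentivirus with either transgene and were kept for a further 6 days before total RNA was extracted and labelled with the Quick Amp kit. On each array the culture's RNA was in the Cy5 channel and a commercial mouse reference RNA (Universal Mouse Reference) was in the Cy3 channel, per the labels, and no array had the dyes swapped. The labels give each array a pair tag and a batch tag. Each of the 4 pairs joins 1 Nr4a1-labelled and 1 GFP-labelled array with the same replicate number, and replicate 4 is the whole of batch 2. The file headers place the 4 GFP-labelled arrays on slide 1, Nr4a1-labelled replicates 1 to 3 on slide 2 and Nr4a1-labelled replicate 4 on slide 3, with 1 scan per slide.

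The scanner files were made with Agilent Feature Extraction 11.0.1.1, per the file headers, and give for every spot and channel a median signal intensity and a local background intensity on a linear scale. They also give background-subtracted, dye-normalised processed signal intensities and their log10 ratio of Cy5 over Cy3, computed by the software before the authors deposited the files. The deposited value table of the series holds 24275 probes with log2 ratios. Its scale, centring and direction are not stated, and they were found by setting each column against the same array's scanner values. The columns correlated with the log2 Cy5 over Cy3 ratios computed here at 0.998 to 1.00 across probes, with slopes of 0.992 to 1.01, and their medians lay between 0.0240 and 0.0312. The table was therefore read as log2 of sample over reference. The submitters' processing notes name Agilent Feature Extraction and limma without versions or settings, and how the authors chose the probes of the table is not given in the sources used here.

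Each array had 44397 spots, of which 43020 were not controls, for 39429 probes. Median Cy5 signals ran from 137 to 194 and median Cy3 signals from 141.5 to 154, over local backgrounds of 29 to 32. Between 60.9% and 69.2% of the spots were well above background in Cy5, and between 62.5% and 69.3% in Cy3, and 0 spots were saturated. The number of arrays limits the precision.

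Median signals were used because the files used here hold no mean signal column. The background was corrected with normexp and an offset of 50, which shrinks the folds of dim probes. Ratios were normalised within each array by loess with control spots at weight 0. Spots marked by the software as outliers were left out, and spots of the same probe were averaged. On Nr4a1-labelled replicate 2, 37 spots had a local background marked as non-uniform, reaching 8509 in Cy5 and 33931 in Cy3. With these spots in, normexp gave mean background terms of -299 and -551 in place of -3.33 and -5.05, so spots with such a background were left out on every array before the correction. That choice was made after seeing the data. The version with all spots, which is the correction as first planned, is given as an added alternative. A probe was tested where Cy5 was well above background on at least 4 of the 8 arrays and each group had at least 3 values. The files give accessions and no gene names, so probes were named through a RefSeq gene table of the GRCm38.p6 assembly, which matched 26581 probes to a symbol and left 12848 under the file's own identifier. For a gene with several probes, the probe with the highest mean Cy5 intensity was used. This left 21116 genes or unnamed transcripts, called features here, 15019 of them with a symbol. Among 1064 genes past the threshold with several probes, 18 had another probe at an unadjusted p under 0.05 in the other direction.

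The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 ratios, with the pair as a fixed block and Benjamini-Hochberg adjustment over all 21116 features at 0.05. The pair tag in the labels was the ground for the block. Deviations of the arrays from their group means correlated within pairs at -0.10, 0.28, -0.016 and 0.43 for replicates 1 to 4. Folds are 2 to the power of the log2 difference. Where 1 group was not well above background on any array, no fold is given.

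Genes named in the text were chosen by a rule fixed before the data were examined. They are the 3 NR4A genes, the 12 largest rises and 12 largest falls among named genes past the threshold with the same sign in all 4 pairs, and the 4 members of smallest p in each of 31 gene lists. Some of these genes and 1 list are not reported here. Other genes named were chosen after their values were seen, either as members of the lists past the threshold or as said where they appear. The lists, also fixed beforehand, cover neuronal, synaptic, metabolic and stress functions and the markers of cell types the cultures could hold. They were tested with camera at a preset correlation of 0.01 and adjusted over the 31 lists, with camera at an estimated correlation and fry beside it. Each list's median was also set against 10000 random lists of its size matched on Cy5 intensity.

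The procedure was tested on simulated data for the comparison of Nr4a1-labelled with GFP-labelled arrays, over 21055 genes. It recovered 71.6% of 67 genes changed by 0.5 log2 units, 95.5% of 67 changed by 1 and 98.5% of 66 changed by 2, with 4.95% false calls among 202, and it made 0 calls where no gene was changed. The simulated noise was independent between genes, few genes were changed and no slide difference was put in. The simulation therefore does not show the share of false calls where genes move together or slides differ. The alternatives tried were the fit without the pair block, with batch as the block and with slide as a random block, other background corrections, normalisations, filters and probe summaries, the Cy5 channel alone, and Agilent's ratio. The authors' table, leaving out each replicate, limma's trend and array weights, other thresholds and the other set tests were also tried. Arrays were compared only between the 2 groups, and nothing was left out beyond the spots and probes described.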

Results

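Gene expression was measured on 8 arrays of cultured mouse hippocampal neurons, 4 labelled as carrying lentiviral Flag-tagged Nr4a1, an activity-induced orphan nuclear receptor, and 4 labelled as carrying lentiviral GFP. The comparison asks which transcripts differ in neurons given Nr4a1, in a series on dendritic spines and excitatory synapses. Levels are log2 ratios of the culture's RNA over a common reference RNA, and differences are Nr4a1-labelled minus GFP-labelled within 4 pairs (n = 4 per group throughout). Errors of differences are limma standard errors.

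The delivered gene was read first. The only Nr4a1 probe (A_51_P239654) gave -2.06, -2.12, -1.90 and -2.49 on GFP-labelled replicates 1 to 4 and -1.32, -2.49, -1.20 and -2.37 on Nr4a1-labelled replicates 1 to 4. The difference was 0.30 ± 0.15 (SE, n = 4), higher in 3 of 4 pairs, with limma adjusted p = 0.196. It passed the test without replicate 2 (0.52, adjusted p = 0.00643) and with median centring in place of loess (0.40, adjusted p = 0.0166), and its adjusted p ran from 0.00643 to 1.00 over all settings tried. Nr4a2 differed by 0.47 ± 0.27 (adjusted p = 0.251), at 1.08 in replicate 1, higher still in replicate 3, and at -0.41 and -0.31 in replicates 2 and 4. Over all settings tried Nr4a2 ran from 0.12 to 0.76, and it too passed the test without replicate 2 and with median centring. The Nr4a3 probe was well above background on 0 of 8 arrays and was not tested. Because the Nr4a1 probe does not separate the groups, and its position relative to the delivered sequence is not known, the arrays are named by their labels.

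Many transcripts nonetheless separated the labelled groups by several-fold. Nrarp, which encodes a Notch-regulated ankyrin repeat protein, rose 5.58-fold, from 1.67 ± 0.11 to 4.15 ± 0.19 (log2 ratio, SD, n = 4), with limma adjusted p = 3.22e-08. Follistatin (Fst), an activin antagonist, rose 4.69-fold, and Acacb, an acetyl-CoA carboxylase, rose 4.51-fold. The neurotrophin receptor gene Ngfr rose 3.92-fold and the neuropeptide gene Nmb 3.99-fold, while Grp, which encodes the related gastrin-releasing peptide, was 9.87-fold lower (5.29 ± 0.20 against 1.99 ± 0.19, SD, n = 4; adjusted p = 3.39e-08). Each of these genes moved the same way in all 4 pairs. The Nrarp call was lost in Agilent's own ratio and with all spots in the background correction, its smallest difference over all settings being 1.86. The Ngfr call was lost with all spots too. With slide as a random block beside the pair term, the Ngfr and Acacb calls were lost.

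The 12 largest rises ran from 2.48 ± 0.07 for Nrarp to 1.84 ± 0.09 for D830030K20Rik on the log2 scale. The aldo-keto reductase gene Akr1b7 was well above background on 0 of 4 GFP-labelled and 4 of 4 Nr4a1-labelled arrays and was higher in all 4 pairs (limma adjusted p = 5.13e-08). Cmbl rose by 2.11 ± 0.06, the zinc transporter gene Slc39a4 by 2.08 ± 0.06, Plcxd2 by 1.91 ± 0.09 and Gm2897 by 1.91 ± 0.06. Gm2897 and D830030K20Rik have close relatives in the genome, and D830030K20Rik stood at -0.10 in Agilent's own ratio.

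After Grp, the largest falls were in Ptx4, a pentraxin gene (-1.97 ± 0.06), and Akr1c18, a steroid-converting aldo-keto reductase with close paralogs (-1.96 ± 0.07). The chemokine-scavenging receptor gene Ackr3 fell by 1.65 ± 0.06 and Trhr, the receptor for thyrotropin-releasing hormone, by 1.64 ± 0.12. Strip2 (-1.59 ± 0.09), Plekhd1 (-1.48 ± 0.06) and Olfml2b (-1.46 ± 0.06) also fell, as did Sla, 2.83-fold lower and well above background on 3 of 4 Nr4a1-labelled arrays. Tiam2, an activator of Rac, fell by 1.47 ± 0.06, Ccdc68 by 1.45 ± 0.07 and the Wnt-enhancing secreted factor gene Rspo3 by 1.44 ± 0.08. The highest adjusted p among the 12 falls was 1.65e-05, for Trhr. Among transcripts without a gene symbol, ENSMUST00000151825 rose by 2.58 and ENSMUST00000125538 fell by 3.17.

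**Figure D1:**
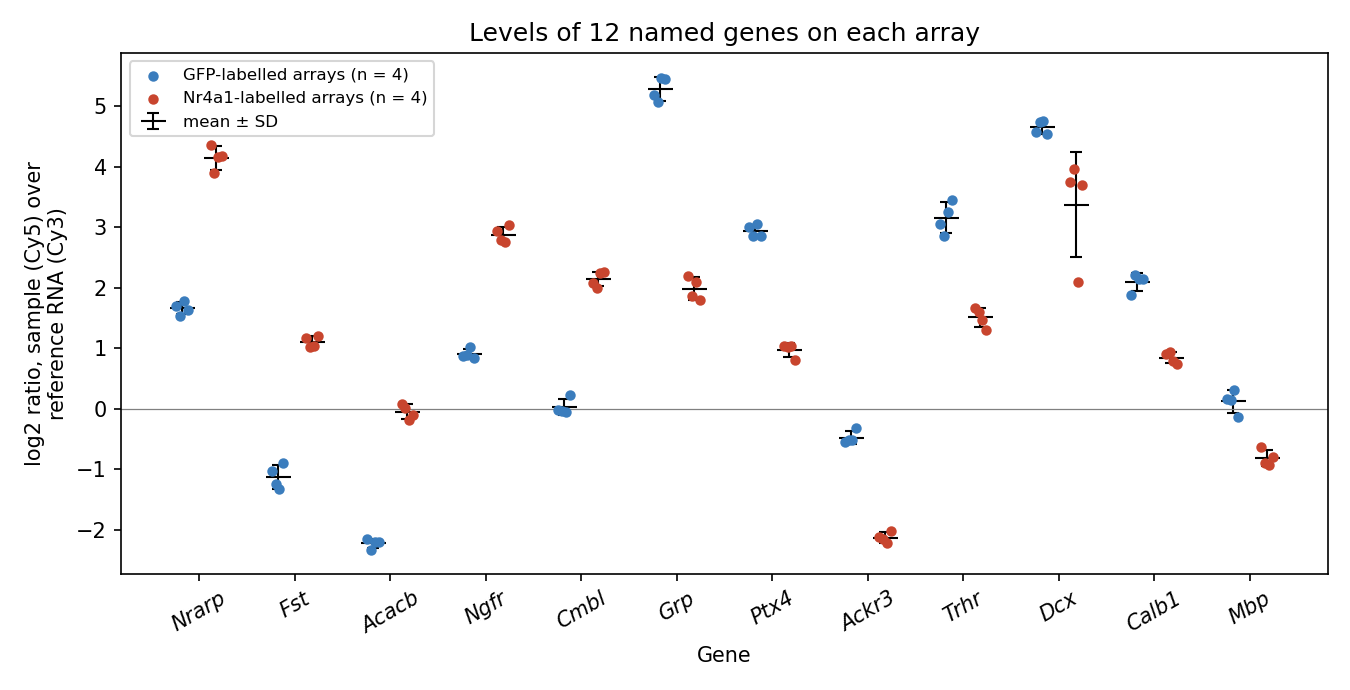
Log2 ratio of culture RNA (Cy5) over reference RNA (Cy3) for 12 named genes on each of the 8 arrays, as points, with the group mean ± SD as bars (n = 4). Nr4a1-labelled and GFP-labelled arrays do not overlap for any gene shown, the widest spread being that of Dcx in the Nr4a1-labelled group.

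Over all 21116 features, 2711 were higher and 2434 lower in Nr4a1-labelled arrays (limma, pair block, adjusted p under 0.05), which is 24.4% of those tested, against 7723 at an unadjusted p under 0.05. Most differences were small, with a median size of 0.32 on the log2 scale among those called, and 112 rises and 50 falls were at least 2-fold. The same sign in all 4 pairs was seen for 2639 of the rises and 2378 of the falls. In batch 1 alone 1989 features were higher and 1888 lower, and batch 2, a single pair, had the same sign for 93.2% of those. Each slide held arrays of 1 group only, and with slide as a random block beside the pair term 8 rises and 4 falls passed, among them Fst, Cmbl, Slc39a4, Nmb, Nrarp, Akr1b7, Grp and Ptx4. Agilent's own ratio gave 1511 rises and 1350 falls, and without replicate 1 there were 1783 rises. The background correction as first planned, with all spots in, gave 130 rises and 98 falls. The counts of 2711 and 2434 thus rest on leaving spots out, a choice made after the data were seen. Median centring in place of loess changed the split to 3462 higher and 1262 lower, so 73.3% of calls were rises against 52.7%. Nothing in the labels says that the 4 replicates were separate cultures, and p-values then measure the spread between these samples, which may be technical.

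Of the 31 gene lists, 8 were called by camera, and each of those calls was lost with an estimated correlation, and each but that of interferon response genes with fry. Without the pair block, 15 of the 35 ways to split the 8 arrays into 4 and 4 called as many lists as the labels did. Proliferation markers had the smallest p, with 15 of 27 measured members higher, 0 lower and 12 not called, or 20 and 0 adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose by 1.26 ± 0.07, the mitotic cyclin gene Ccnb1 by 0.70 ± 0.07, Birc5 (survivin) by 0.53 ± 0.07 and Mki67 by 0.39 ± 0.07. The list median was 0.22, with camera adjusted p = 1.11e-07, and adjusted p = 0.768 with an estimated correlation. Of 22 astrocyte markers 6 were higher and 2 lower, and of 16 oligodendrocyte lineage markers 7 and 2. Of 16 microglia markers 0 were higher and 2 lower, as given further on.

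Cholesterol synthesis genes were lower in 14 of 25 members, higher in 2 and not called in 9 (17 lower and 2 higher adjusted over the list alone), with a median of -0.30. The cholesterol carrier gene Stard4 fell by 0.69 ± 0.07, and the mevalonate pathway enzyme genes Mvk, Mvd and Fdps fell by 0.67 ± 0.09, 0.58 ± 0.06 and 0.57 ± 0.07. Tm7sf2, by contrast, rose by 0.36 ± 0.09 and Hsd17b7 by 0.26 ± 0.07. Camera gave adjusted p = 2.26e-05, and adjusted p = 0.768 with an estimated correlation.

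Immediate early and activity-regulated genes, the transcripts that neuronal firing induces, were higher in 14 of 35 measured members, lower in 1 and not called in 20 (16 and 1 adjusted over the list alone). Without the pair block 6 were higher, with batch as the block 7 and with all spots in the background correction 0. The prohormone convertase gene Pcsk1 rose by 0.96 ± 0.08, the ERK phosphatase gene Dusp6 by 0.88 ± 0.09, Fosl2 by 0.78 ± 0.14 and Egr4 by 0.60 ± 0.12, and Jun was the member that fell (-0.53 ± 0.13). The Egr4 call was lost in Agilent's own ratio, where its difference was -0.45. The Pcsk1 call was lost there too, and its smallest difference over all settings was 0.27. With all spots in the background correction the calls of Pcsk1, Dusp6, Fosl2 and Egr4 were all lost. The same held with slide as a random block beside the pair term. Camera gave adjusted p = 0.00117, and adjusted p = 0.768 with an estimated correlation. The list call was lost without replicate 3 (adjusted p = 0.0837, within a range of 4.01e-08 to 0.768 over all settings tried) and with slide as a random block beside the pair term (adjusted p = 0.0928), and the list medians were 0.63, 0.02, 0.67 and 0.05 in replicates 1 to 4. Arc, chosen after its values were seen, differed by 2.13, 0.14, 2.41 and 0.68 in replicates 1 to 4 (1.34 ± 0.31, adjusted p = 0.0113), and its call was lost without replicate 1. Fos, at 1.73, -0.29, 1.94 and 0.09, was not called (adjusted p = 0.0743). It was called without replicate 2, with median centring and on the authors' value table, and its difference ran from 0.51 to 1.25 over all settings.

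**Figure D2:**
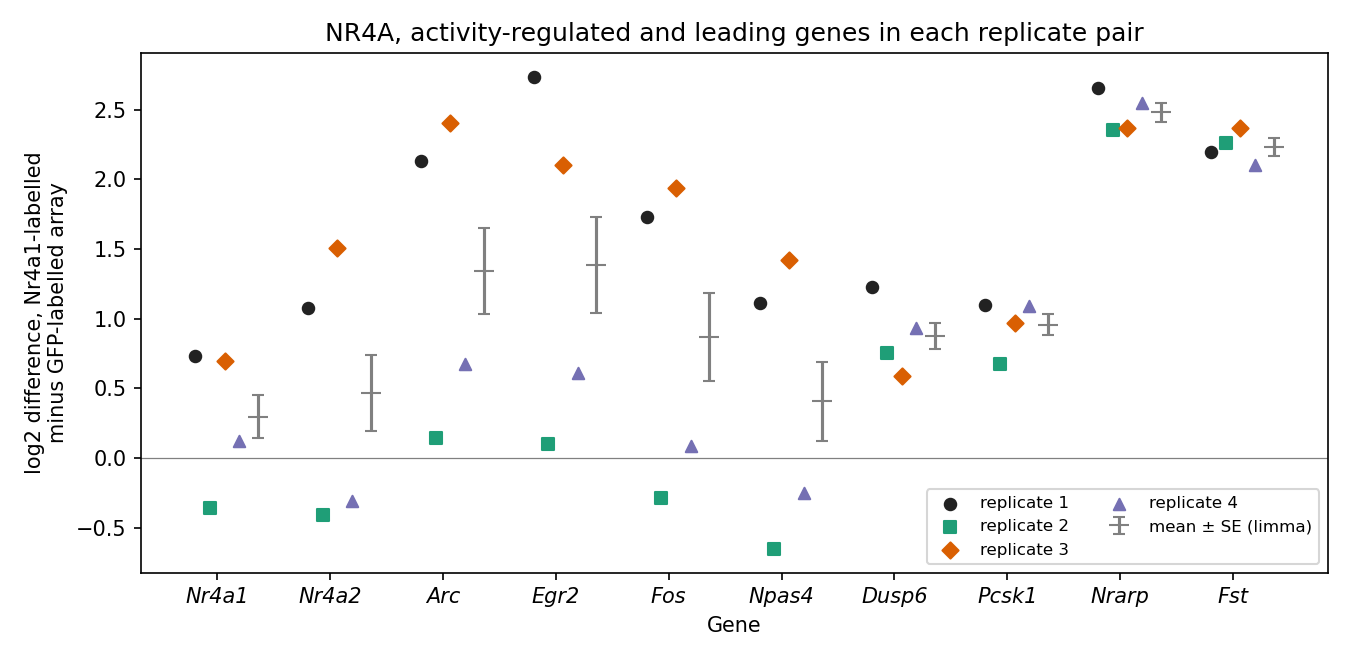
Log2 difference, Nr4a1-labelled minus GFP-labelled, in each of the 4 replicate pairs (symbols) and its mean ± SE from limma (grey) for NR4A, activity-regulated and leading genes. Nr4a1, Nr4a2, Arc, Egr2, Fos and Npas4 were higher in replicates 1 and 3 than in 2 and 4, whereas Pcsk1, Nrarp and Fst lay between 0.67 and 2.65 in every pair.

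Interferon response genes were higher in 9 of 30 measured members, lower in 2 and not called in 19 (10 and 2 adjusted over the list alone), with a median of 0.07. The members that rose most were the immunoproteasome subunit genes Psmb8 (1.11 ± 0.07) and Psmb9 (0.65 ± 0.06), B2m (0.75 ± 0.07) and the guanylate-binding protein gene Gbp3 (0.65 ± 0.07). The peptide transporter gene Tap1 rose by 0.39 ± 0.08. Camera gave adjusted p = 0.0150, and adjusted p = 0.768 with an estimated correlation, and the call was lost in the Cy5 channel alone (adjusted p = 0.128). Microglia markers did not rise beside them, 0 of 16 measured members being higher and 2 lower.

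Other nuclear receptors rose more often than they fell, 13 of 32 measured members of the list of nuclear receptors and coregulators being higher, 2 lower and 17 not called (16 and 4 adjusted over the list alone), with a median of 0.15. Nr2f2 (COUP-TFII) rose by 0.87 ± 0.09, Rorb by 0.67 ± 0.06, Rora by 0.62 ± 0.07 and Nr1d2, a circadian repressor gene, by 0.56 ± 0.07. The mineralocorticoid receptor gene Nr3c2 fell by 0.42 ± 0.06. Camera gave adjusted p = 0.0227, and adjusted p = 0.768 with an estimated correlation, and the call was lost on the authors' value table (adjusted p = 0.190).

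Presynaptic vesicle genes were lower in 9 of 34 measured members, higher in 3 and not called in 22 (13 and 3 adjusted over the list alone), with a median of -0.13. The fusion genes Stx1a and Cplx2 fell by 0.54 ± 0.06 and 0.50 ± 0.06 and the vesicle protein gene Synpr by 0.63 ± 0.08, whereas the priming factor gene Unc13b rose by 0.90 ± 0.08 and the vesicular glutamate transporter gene Slc17a6 by 0.59 ± 0.07. The Slc17a6 call was lost in Agilent's own ratio and with all spots in the background correction, and its smallest difference over all settings was 0.042. Camera gave adjusted p = 0.0285, and adjusted p = 0.768 with an estimated correlation. GABA receptors and inhibitory postsynaptic genes were lower in 6 of 20 members, higher in 1 and not called in 13 (10 and 2 adjusted over the list alone), with a median of -0.14. Glra2 fell by 0.64 ± 0.08, Gabbr2 by 0.37 ± 0.07 and Gphn (gephyrin), the inhibitory scaffold, by 0.33 ± 0.06, and Gabrg1 rose by 0.38 ± 0.07 (-0.19 with all spots in the background correction). Camera's adjusted p was 0.0424, with adjusted p = 0.768 with an estimated correlation. Calcium and cAMP signalling genes were lower in 14 of 45 members, higher in 4 and not called in 27 (15 and 4 adjusted over the list alone), with a median of -0.12. The calcium buffer genes Calb1 and Calb2 fell by 1.25 ± 0.08 and 0.92 ± 0.10 and Camkk2 by 0.52 ± 0.07, while Camk2d rose by 1.14 ± 0.07. The Calb2 call was lost in Agilent's own ratio and with all spots in the background correction. Its smallest difference over all settings was -0.37. For this list camera's adjusted p was again 0.0424, and adjusted p = 0.768 with an estimated correlation. These 3 lists kept their direction in all 27 other settings, and their call in 18, 15 and 13 of them.

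Genes of excitatory synapses, dendritic spines and their cytoskeleton moved in both directions without a list call. Postsynaptic scaffold and adhesion genes were higher in 4 and lower in 7 of 39 members (4 and 7 adjusted over the list alone, camera adjusted p = 0.140). Lrrtm2, an excitatory synapse organiser, fell by 0.95 ± 0.09, Homer3 by 0.52 ± 0.07 and Dlg4 (PSD-95) by 0.26 ± 0.06, while Slitrk1 rose by 0.48 ± 0.09 (-0.28 with all spots in the background correction). The Lrrtm2 call was lost in Agilent's own ratio and with all spots in the background correction. Its smallest difference over all settings was -0.34. Glutamate receptors and auxiliary subunits were higher in 7 and lower in 10 of 33 members (7 and 10 adjusted over the list alone, adjusted p = 0.331), with Grik3 rising by 1.22 ± 0.17 and the AMPA receptor auxiliary gene Cnih3 falling by 0.62 ± 0.07. Both calls were lost in Agilent's own ratio, with all spots in the background correction and with slide as a random block beside the pair term. At their smallest over all settings the differences were 0.49 for Grik3 and -0.061 for Cnih3. The median of the glutamate receptor list was -0.06 and its mean 0.0013. Actin cytoskeleton genes were higher in 7 and lower in 16 of 66 members (8 and 17 adjusted over the list alone, adjusted p = 0.277), including falls of Actn2 by 0.85 ± 0.06, Limk1 by 0.57 ± 0.07 and Tmod1 by 0.56 ± 0.06. Myl9 of the same list rose by 0.77.

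Axon guidance and cell adhesion genes were higher in 12 and lower in 18 of 59 members (12 and 19 adjusted over the list alone, adjusted p = 0.331). The guidance cue gene Slit2 rose by 1.82 ± 0.10 and Slit3 by 0.79 ± 0.07, while the adhesion gene Cntn4 fell by 0.71 ± 0.07 and the semaphorin receptor gene Plxna3 by 0.70 ± 0.07. Voltage-gated ion channels were higher in 8 and lower in 8 of 48 members (8 and 8 adjusted over the list alone, adjusted p = 0.777), the potassium channel partner Kcnip1 rising by 0.90 ± 0.06 and Kcnip2 falling by 0.94 ± 0.07. With all spots in the background correction both calls were lost. The Kcnip2 call was lost in Agilent's own ratio too, and its smallest difference over all settings was -0.36. Neuropeptide and neuromodulator genes were higher in 3 and lower in 8 of 29 members (3 and 11 adjusted over the list alone, adjusted p = 0.108). The natriuretic peptide gene Nppc rose by 1.83 ± 0.07 but stood at -0.75 in Agilent's own ratio, and the neuropeptide Y receptor gene Npy1r fell by 0.88 ± 0.08.

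Camera called none of the following lists of cell type markers, though oligodendrocyte lineage markers passed fry (adjusted p = 0.0396, direction up). Pan-neuronal markers were higher in 3 and lower in 6 of 20 members (4 and 11 adjusted over the list alone, camera adjusted p = 0.0679), Dcx (doublecortin) falling by 1.28 ± 0.26 (-0.82 without replicate 3) and Thy1 by 0.36 ± 0.06. Glutamatergic and pyramidal neuron markers were higher in 5 and lower in 9 of 24 (5 and 10 adjusted over the list alone, adjusted p = 0.122), with Bok rising by 1.70 ± 0.06 and Wfs1 by 0.79 ± 0.07 while Spink8 fell by 1.03 ± 0.08. The Spink8 call was lost in Agilent's own ratio, and its smallest difference over all settings was -0.28. GABAergic interneuron markers were higher in 3 and lower in 4 of 25 (3 and 4 adjusted over the list alone, adjusted p = 0.331), with Dlx1 rising by 0.41 ± 0.07 and Htr3a falling by 0.49 ± 0.06. Of 16 oligodendrocyte lineage markers, 7 were higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.108). The precursor genes Pdgfra and Gpr17 rose by 0.76 ± 0.06 and 0.97 ± 0.07, while Mbp, a gene of mature myelin, fell by 0.94 ± 0.09. Gpr17 was well above background on 1 of 4 GFP-labelled arrays. The median of this list was 0.0015 and its mean 0.23. Astrocyte markers were higher in 6 and lower in 2 of 22 (7 and 2 adjusted over the list alone, adjusted p = 0.589), with a rise of Vim by 0.61 ± 0.06, a median of -0.0088 and a mean of 0.058. Microglia markers included a fall of Csf1r by 0.75 ± 0.07 (0 higher and 2 lower adjusted over the list alone, adjusted p = 0.428). Fibroblast and meningeal markers were higher in 1 and lower in 7 of 19 (1 and 9 adjusted over the list alone, adjusted p = 0.0804), Lum falling by 1.00 ± 0.08 and Dcn by 0.59 ± 0.07. Endothelial and mural markers were higher in 3 and lower in 1 of 12 (3 and 1 adjusted over the list alone, adjusted p = 0.696), with Flt1 rising by 0.58 ± 0.06. Choroid plexus and ependymal markers were higher in 2 and lower in 2 of 10 (2 and 2 adjusted over the list alone, adjusted p = 0.777), with a fall of Sostdc1 by 1.34 ± 0.08, a median of 0.054 and a mean of -0.11.

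**Figure D3:**
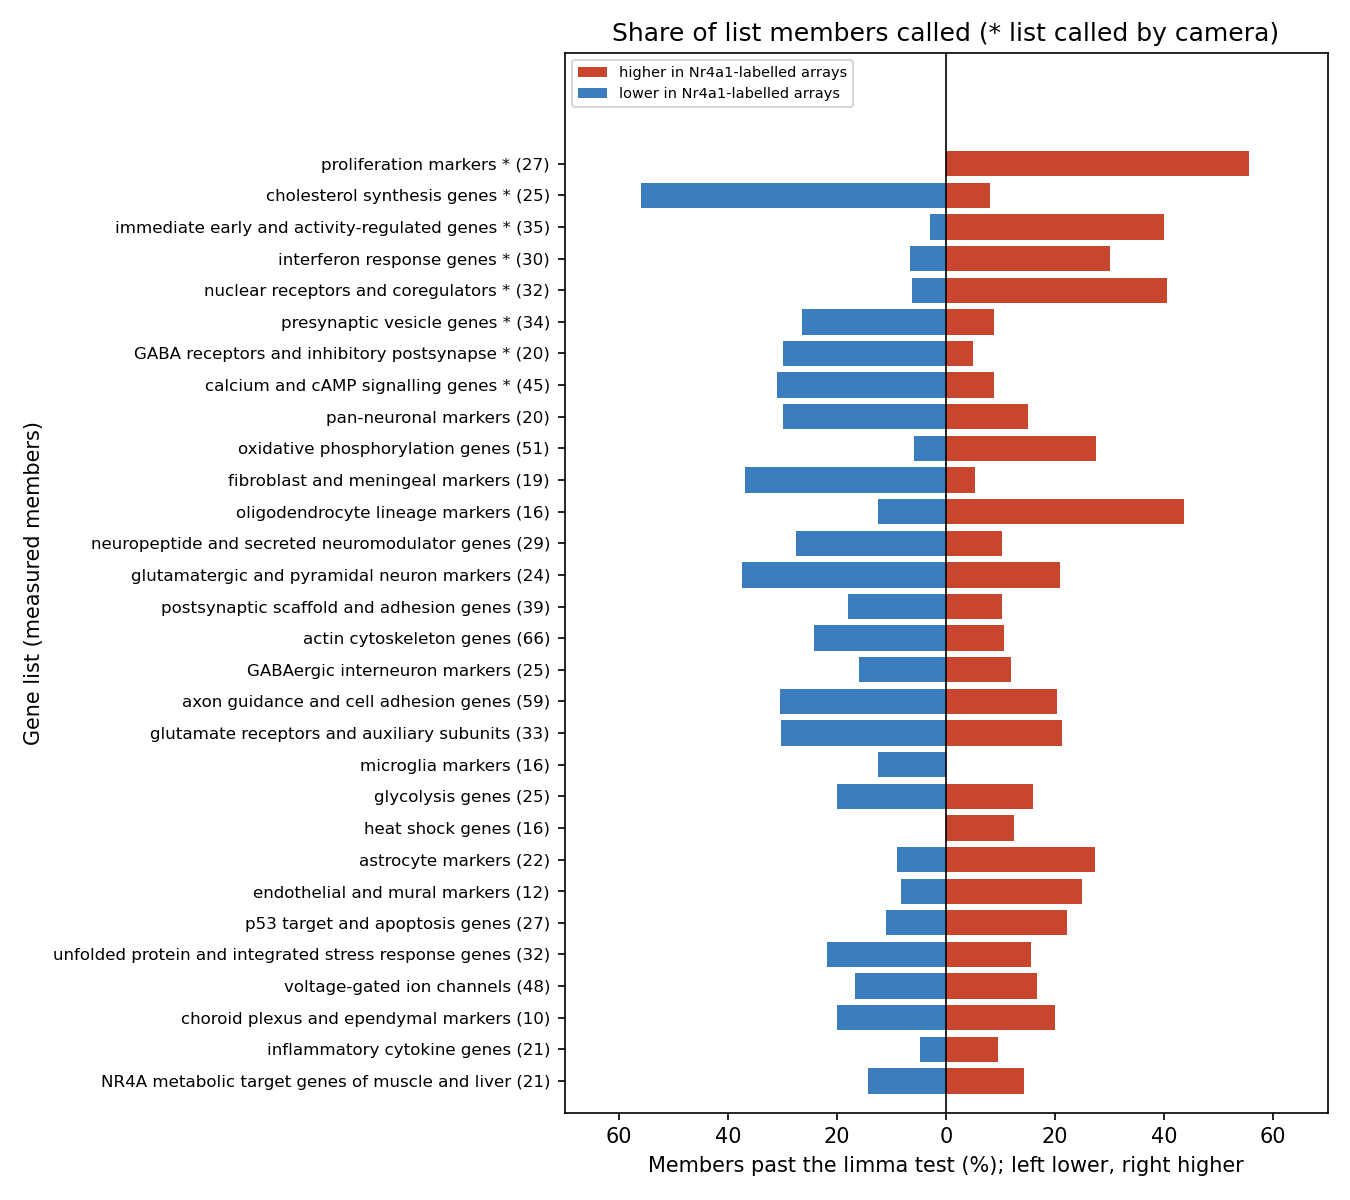
Share of the measured members of each of 30 gene lists that were higher (right) or lower (left) in Nr4a1-labelled arrays by limma, in percent of the members measured (number in brackets), with an asterisk at lists called by camera at the preset correlation. Proliferation markers had 15 members higher and 0 lower, and cholesterol synthesis genes 2 higher and 14 lower.

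The other metabolic lists and the stress lists had no camera call. Oxidative phosphorylation genes were higher in 14 and lower in 3 of 51 members (14 and 3 adjusted over the list alone, camera adjusted p = 0.0804), with Ndufs4 rising by 0.38 ± 0.06 and Sdha by 0.35 ± 0.06. Glycolysis genes were higher in 4 and lower in 5 of 25 (4 and 6 adjusted over the list alone, adjusted p = 0.478), with Pfkp falling by 0.75 ± 0.06. Metabolic genes that NR4A receptors control in muscle and liver were higher in 3 and lower in 3 of 21 (3 and 3 adjusted over the list alone, adjusted p = 0.967), the glucose transporter gene Slc2a4 rising by 0.96 ± 0.06 and Pgam2 falling by 0.71 ± 0.06. Their median was -0.023 and their mean 0.0078. Unfolded protein and integrated stress response genes were higher in 5 and lower in 7 of 32 (7 and 8 adjusted over the list alone, adjusted p = 0.756), Ddit4 falling by 0.78 ± 0.11. Heat shock genes were higher in 2 and lower in 0 of 16 (2 and 0 adjusted over the list alone, adjusted p = 0.478), Dnajb1 rising by 0.54 ± 0.12. Genes of p53 and apoptosis were higher in 6 and lower in 3 of 27 (8 and 4 adjusted over the list alone, adjusted p = 0.696), Plk2 rising by 1.08 ± 0.16 and Perp falling by 0.54 ± 0.06, with a median of -0.00059 and a mean of 0.057. Inflammatory cytokine genes were higher in 2 and lower in 1 of 21 (2 and 1 adjusted over the list alone, adjusted p = 0.967), Serpina3n falling by 0.69 ± 0.07. Their median was -0.011 and their mean -0.0091, while camera's direction was up. By fry, which tests whether the genes of a list move on balance one way, the interferon, oligodendrocyte lineage and p53 lists had adjusted p = 0.0396.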

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

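The tests of a swapped array, of the probe's reach and of a lower share of neurons, and the count of splits for each list, were chosen only after the result was seen. The other tests below were fixed before.

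Many genes differed between the labelled groups (2711 higher, 2434 lower). Without the pair block the labels gave 4475 genes, 1 of the 35 splits of the 8 arrays gave as many (the labels themselves) and the highest other split gave 0. Every other split mixes both groups, so a difference between them widens the spread within each side and makes a low count likely. The share of 1 in 35 is under the 0.05 set beforehand and is the smallest these splits can give. It argues against an arbitrary split of the arrays as the source of the count, but the slides part the arrays the same way. With the block, the 8 ways to swap labels within pairs are too few for a share under 0.05, the labels being the 1 way with 5145 genes and the highest other giving 0. A difference limited to batch 1 is argued against, since 93.2% of the 3877 genes called in batch 1 alone had the same sign in batch 2. The GFP-labelled array of batch 2 lay on slide 1 with those of batch 1, so a difference of slide 1 could give the same agreement. A slide or hybridisation difference could not be told apart from the labels: the Cy3 reference moved by only 0.0545 of the ratio (95% interval 0.0460 to 0.0630), but every slide held 1 group, and a difference of the Cy5 side alone between slides would leave Cy3 still, so the bound set for that test was wrong for this design.

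The Nr4a1 probe was not clearly higher in the Nr4a1-labelled arrays (0.30 ± 0.15, SE, n = 4). A swap of single arrays is argued against, since 0 of the 8 arrays were closer to an array of the other group than to one of their own. This says nothing of a swap of the groups as a whole, and arrays that share a slide may be alike for that reason. Weak gene transfer in replicate 2, where the probe fell, and replicate 4, where it rose least, could not be settled. The slopes of their differences on those of replicates 1 and 3 were 0.861 and 0.830, over the genes called in replicates 1 and 3. These slopes argue against weak transfer only if the differences come from the transgene. A slide difference shared by all pairs would give such slopes too, since slide 1 held every GFP-labelled array and no Nr4a1-labelled one. Whether the probe reads the delivered sequence stays open: in 0 of 4 pairs was it at least 2-fold higher, and neither its position nor the delivered sequence is known here. A low level of the transgene stays open as well.

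Proliferation markers were higher (15 of 27, median 0.22). The median was exceeded in a share of at most 1e-04 of random lists, the smallest the 10000 draws can give, but genes that move together make such lists too narrow, and with the estimated correlation of 0.511 camera's unadjusted p was 0.178. In 1 of the 35 splits, the labels themselves, the list's median difference was as large (highest other 0.20). A larger share of dividing glia could not be told apart from a change within the cells present. The highest median of 5 non-neuronal lists was 0.0512 of the proliferation median. Against that, 7 of 16 oligodendrocyte lineage members were higher and 2 lower. A lower share of neurons, which would raise the markers of every other cell type alike, could not be settled. In 3 of those 5 lists (microglia, fibroblast and endothelial) the interval of the median lay wholly below that of the proliferation markers. Of the 85 members of the 5 lists 17 were called higher and 14 lower, although 0 of the 5 intervals lay wholly below 0. An even rise of the other cell types was thus not seen. The neuronal lists leaned lower, however, with medians of -0.16 for pan-neuronal markers (interval -0.22 to -0.030), -0.15 for glutamatergic markers (-0.27 to 0.028) and -0.10 for interneuron markers (-0.16 to 0.074). That Nr4a1 itself raised the proliferation genes was not tested.

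As many as 15 of the 35 splits called as many lists as the labels did without the block (6, highest other 17), so chance cannot be excluded for the count of lists. By list, the labels gave the largest median difference of the 35 splits for 6 of the 31 lists: proliferation, cholesterol synthesis, nuclear receptors, presynaptic vesicle, GABA receptor and calcium genes. For immediate early genes 12 of the 35 splits gave a median as large, and for interferon genes 5.

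Single arrays far from the other 3 of their group were looked for in 437 groups of 4 values and found in 19, against about 1 in 20 by chance. That is no more than chance would give, so a gene listed here need not mark a real departure. The value given is the gap to the nearest array as a share of the group's whole range. Nr4a1-labelled replicate 2 stood apart in its number of spots with a marked background (1, 37 spots) and in its highest local background in Cy5 (0.999) and Cy3 (1.00). It also stood apart for D830030K20Rik (0.899), Rrm2 (0.852), Cplx2 (0.922) and Hey1 (0.945). Nr4a1-labelled replicate 3 was low for Dcx (0.860), at 2.09 against 3.70 to 3.96, and for Gipr (0.904). Nr4a1-labelled replicate 4 stood apart for Eno3 (0.878), Ptprf (0.920), Ptx4 (0.930) and Gm5797 (0.870). GFP-labelled replicate 4 stood apart for Cmbl (0.914), Ndufs4 (0.944), Camkk2 (0.895) and Ackr3 (0.846), GFP-labelled replicate 2 for Rspo3 (0.871) and GFP-labelled replicate 3 for Dll3 (0.869).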

How the results depend on the processing

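Leaving spots with a marked background out of the correction was chosen after seeing the data. The version with all spots, the correction as first planned, was therefore added to the alternatives then. The other alternatives were fixed before. Over the alternatives, 4525 of the values of named genes kept their side of the threshold, 494 lost the call, 32 gained one and 9 reversed. Those 4525 kept their direction where they were called, while values not called in either fit were counted whatever their sign. The 8 list calls kept their direction in all 27. Grp, Fst, Cmbl, Slc39a4, Nmb and Ptx4 kept their calls in all 26, and proliferation and cholesterol synthesis genes in 25 of 27, all but camera with an estimated correlation and fry. The fit with no replicate block gave 2350 higher and 2125 lower genes and 6 lists, against 2711, 2434 and 8 with the pair block. It ended the calls of the GABA receptor and calcium lists and of 7 named genes. Loess with Aquantile moved nothing, by construction, since between-array scaling of that kind leaves the ratios as they are. The 1.5-fold threshold gives no list count.

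With slide as a random block and the pair term, 8 genes were higher, 4 lower and 5 lists called. The consensus correlation within slides was then 0.862 and was -0.0234 without the pair term, where 2522 and 2287 genes passed. Beside the pair and group terms, the value of 0.862 rests on the contrast of slide 3 with slide 2. Slide 3 held 1 array, Nr4a1-labelled replicate 4 of batch 2, so slide and batch cannot be told apart there. The 12 calls left are thus no measure of the size of a slide difference, which stays possible. Agilent's ratio gave 1511 higher and 1350 lower genes, with D830030K20Rik at -0.10, Nppc at -0.75, Egr4 at -0.45 and Dll3 at -0.26. Median centring gave 1262 lower genes, 5 lists and Nr4a1 at 0.40, past the threshold. The version with all spots gave 130 higher and 98 lower genes and 16 lists, with Egr4 at -0.054, Slitrk1 at -0.28, Grm3 at -0.13, Gabrg1 at -0.19 and Abhd6 at -0.012. There normexp failed on 1 array, Nr4a1-labelled replicate 2, with a mean background term of -299 in Cy5. The Cy5 channel alone and limma's trend gave 5 lists each, and no filter gave 13. At least 1.5-fold left 402 and 297 genes, and an adjusted p under 0.01 left 1495, 1211 and 3 lists, by construction. Camera with an estimated correlation gave 0 lists, and 0 at an unadjusted p under 0.05, and fry gave 3. Leaving out each replicate gave 1783 (without replicate 1) to 2597 higher genes, 4 (without replicate 3) to 13 lists (without replicate 4) and Nr4a1 at 0.15 to 0.52, called without replicate 2. Where no construction is named, the cause was not tested. Between 60.9% and 69.2% of spots were well above background in Cy5, which limits what can be said of dim genes.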

Other observations

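The genes in this part were chosen after their values were seen, and so was the test of neighbouring genes. Peptide receptor genes beside Trhr and Npy1r moved in both directions. Of 21 measured, those 2 included, 11 were lower, 3 higher and 7 not called (limma, pair block), and the set as a whole was not tested. Prokr2, a prokineticin receptor, fell by 1.08 ± 0.07 (SE, n = 4), Gipr by 1.04 ± 0.11 (well above background on 1 of 4 Nr4a1-labelled arrays), the somatostatin receptor gene Sstr1 by 0.97 ± 0.12 and the orexin receptor gene Hcrtr1 by 0.86 ± 0.14. The melanocortin receptor gene Mc4r fell by 0.83 ± 0.07 and Tacr3 by 0.81 ± 0.07, whereas the neuropeptide Y receptor genes Npy6r and Npy2r rose by 1.43 ± 0.07 and 1.01 ± 0.08. Npy6r was well above background on 2 of 4 GFP-labelled arrays. The neuromedin B receptor gene Nmbr fell by 0.66 ± 0.11 and its orphan relative Brs3 rose by 1.46 ± 0.09. The retinoic acid-degrading enzyme genes Cyp26b1 and Cyp26a1 fell by 1.05 ± 0.11 and 0.91 ± 0.07, and the retinoic acid receptor gene Rarb rose by 0.49 ± 0.07. Cyp26b1 and Cyp26a1 moved the same way in all 4 pairs.

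Among 15 measured Notch-related genes, 7 were higher, 1 lower and 7 not called. Beside Nrarp, the ligand genes Dll1 and Jag1 rose by 0.69 ± 0.09 and 0.44 ± 0.06, and the smaller differences of Lfng (0.20 ± 0.06, adjusted p = 0.0335) and Hes1 (0.23 ± 0.07, adjusted p = 0.0415) were past the limma threshold. Lfng lost its call without any 1 of the 4 replicates and Hes1 without replicate 1, 2 or 3, and without replicate 1 the 7 higher genes were 4. Hey1, a target of the pathway, fell by 0.31 ± 0.06, and Hes5, another target, was not called (0.18 ± 0.10, adjusted p = 0.198). Of the 15019 genes with a place in the annotation, the longest run of neighbouring measured genes called in 1 direction held 10 genes, and the next longest 6. The 10 are predicted genes with close relatives among each other, Gm2897, D830030K20Rik, Gm10413, Gm3020, Gm3002, Gm5796, 4930555G01Rik, Gm10406, Gm3696 and Gm5797, all higher in all 4 pairs. Gm3002 was well above background on 0 of 4 GFP-labelled arrays, and the other 9 rose by 0.98 to 1.91. D830030K20Rik stood at -0.10 in Agilent's ratio. In 10000 permutations of the calls over the genes the longest run was 9, so the share with a run as long was 1e-04 at most, the smallest they can give. Probe sequences were not compared, so how many of the 10 transcripts changed is not known.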
